A study of Mus musculus with 26 samples.

How the data were processed

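RNA was measured by sequencing in 26 samples of 3 kinds. The first was mouse small intestinal spheroids, which are hollow epithelial cultures grown in Matrigel with a conditioned medium that supplies Wnt, R-spondin and Noggin. The second was crypt-enriched mouse small intestine after tamoxifen. The third was Caco-2, a human colorectal adenocarcinoma line used as a model of intestinal epithelium. The spheroids were labelled Fgfr1op knockout (KO) or wild type (WT), 4 mice in each group per the series' design text, at day 3 after hydroxytamoxifen (250 nM), the drug that switches on an inducible recombinase. The Caco-2 cells carried a doxycycline-inducible lentiviral vector with a hairpin against Fgfr1op (shFgfr1op) or a non-targeting hairpin (scramble), with 3 samples in each group at day 3 after doxycycline. No label says that the Caco-2 samples came from separate cultures, so p-values there measure only the spread between these samples, which may be technical.

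The authors deposited 1 table of whole-number counts of reads per gene for each kind of sample. Per the submitters' processing notes, STAR and DESeq2 were used and the mouse build was mm10, with no versions. The labels give the mouse organism and build for Caco-2 as well, but the Caco-2 table holds human Ensembl identifiers, so its build is not given in the sources used here and no human coordinates are printed. Whether reads were counted by strand, and how reads that map to several places were treated, is not given in the sources used here. Reads of a gene and an overlapping or near-identical copy may therefore be split between them, and members of close families such as Naip6, Clca3b, Oas1a and HLA-B are uncertain in this respect. Spheroid columns were matched to samples by title. Caco-2 columns were matched by the catalogue numbers of the hairpins in the labels. In the crypt table the 12 per-sample columns show genotype and a running number but not the day, so they were matched to no sample and were not used. The crypt comparisons at days 6 and 9 were not analysed here.

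There were 40757 entries for spheroids and 55209 for Caco-2. Entries that repeated an identifier held the same counts and were removed (276 and 116), which left 40481 and 55093 genes. Of the mouse identifiers, 40254 were found in GENCODE M21, whose assembly is that of mm10, and coordinates come from there. Total counts per library ran from 44152608 to 67630241 in the 8 spheroid libraries and from 37281821 to 50965004 in the 6 Caco-2 libraries. Replicates of 1 group were compared by a chi-square statistic over genes with at least 20 counts in a pair. It ran from 26.71 to 97.41 per degree of freedom in spheroids and from 3.98 to 9.58 in Caco-2, so no pair agreed within sampling noise and every library was counted once.

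Each comparison was fitted on its own table with edgeR 4.0.16 (R 4.3.3). Genes were filtered with filterByExpr, library sizes were scaled by TMM, and the quasi-likelihood F test with robust dispersions was followed by Benjamini-Hochberg adjustment, with a gene called at an adjusted p below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are given as CPM, the count of a gene relative to the TMM-scaled total of its library, on the usual scale of edgeR. For the target gene an exact two-sided permutation test on log2 CPM stands beside the model. In all, 28 gene lists with 814 entries were fixed before the data were examined, and 718 of the entries were tested in spheroids and 642 in Caco-2. Human members were taken by upper-case symbol or by a second symbol given in the list. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, again with Benjamini-Hochberg adjustment. Mouse and human genes were matched by identical upper-case symbol.

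Genes are named by a rule fixed before the data were examined. It takes the target, then the 8 largest rises and the 8 largest falls in log2 fold change among genes called with a mean log2 CPM of at least 2, no overlap between the groups' libraries and no predicted-gene name. It adds the 3 members of smallest p in each list that camera called or that had at least 3 members called, and in any case the 2 members of smallest p in the stem cell, centrosome, actomyosin and p53 lists. The text gives a selection of the genes so named, and says where a gene was chosen otherwise. Some genes that the rule takes are not reported here by name, and counts over lists include them.

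The alternatives were RLE size factors, no filter on low counts, a filter of at least 1 CPM in as many libraries as the smallest group, each library left out in turn, the replicate number as a block, limma voom with sample quality weights, DESeq2 1.42.0, an absolute log2 fold change of at least 1, camera with an estimated correlation, the directional and mixed tests of fry, and a threshold of 0.01 for shared calls. DESeq2 for the target gene alone was added after the data were seen. Camera with an estimated correlation also uses only the residual degrees of freedom of the fit, which are few here. A call lost there need not come from correlation between members. The steps were tested on simulated counts drawn for the real genes, with 200 genes changed by known folds before filtering. In the spheroid simulation edgeR was run on 15716 genes and recovered 46.9% of the genes changed 1.5-fold, 72.7% of those changed 2-fold and 90.8% of those changed 4-fold, and 10 of its 147 calls were unchanged genes. In the Caco-2 simulation it was run on 18529 genes and recovered 55.4%, 78.8% and 98.5%, and 5 of its 158 calls were unchanged genes. DESeq2 called 185 genes in the spheroid simulation, of which 33 were unchanged, and 151 in the Caco-2 simulation, of which 4 were unchanged. With no gene changed, edgeR called 0 genes in either simulation. When 1 list was shifted, camera called it and 0 of the other 27 lists in both. Each gene was drawn independently there, so the members of a simulated list were not correlated. In the real data they can be, with an estimated correlation of 0.83 for the spheroid glycolysis and hypoxia list. The simulation therefore cannot show how often camera calls unchanged lists with correlated members. Python 3.11.15 was used to read the tables and to draw the plots.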

Results

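The data were counts of RNA sequencing reads per gene in mouse small intestinal spheroids (4 KO and 4 WT libraries) and in Caco-2 cells (3 shFgfr1op and 3 scramble libraries). Total counts per library were 51459939 to 63981065 in spheroid KO and 44152608 to 67630241 in spheroid WT. In Caco-2 they were 37281821 to 43876634 in shFgfr1op and 37989227 to 50965004 in scramble. The study is about a centrosomal defect of intestinal stem cells. Fgfr1op, also called Cep43 or FOP, encodes a protein of the centrosome that takes part in anchoring microtubules and in building cilia. The comparisons ask which genes change when it is deleted in spheroids or knocked down in Caco-2.

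Fgfr1op itself was lower in both systems. In spheroids the gene (ENSMUSG00000069135, chromosome 17, 8165501 to 8196804, mm10) had 17.4 ± 1.98 CPM in KO and 23.2 ± 1.12 CPM in WT (SD, n = 4 each), which is 25.1% lower. The KO libraries lay between 15.0 and 19.8 CPM and the WT libraries between 21.7 and 24.4 CPM, without overlap, and the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 can give. The log2 fold change was -0.42 ± 0.095 (SE), with an adjusted p of 0.117 in edgeR over all genes tested, so the gene did not pass there. Which exons were deleted is not given in the sources used here, and reads from the rest of the transcript count towards these values. In Caco-2, FGFR1OP (ENSG00000213066) had 6.82 ± 0.41 CPM in shFgfr1op and 15.7 ± 0.21 CPM in scramble (SD, n = 3 each), which is 56.5% lower. The log2 fold change was -1.20 ± 0.094, with an edgeR adjusted p of 1.65e-14. The exact permutation p was 0.1, the smallest that 3 against 3 can give.

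**Figure D1:**
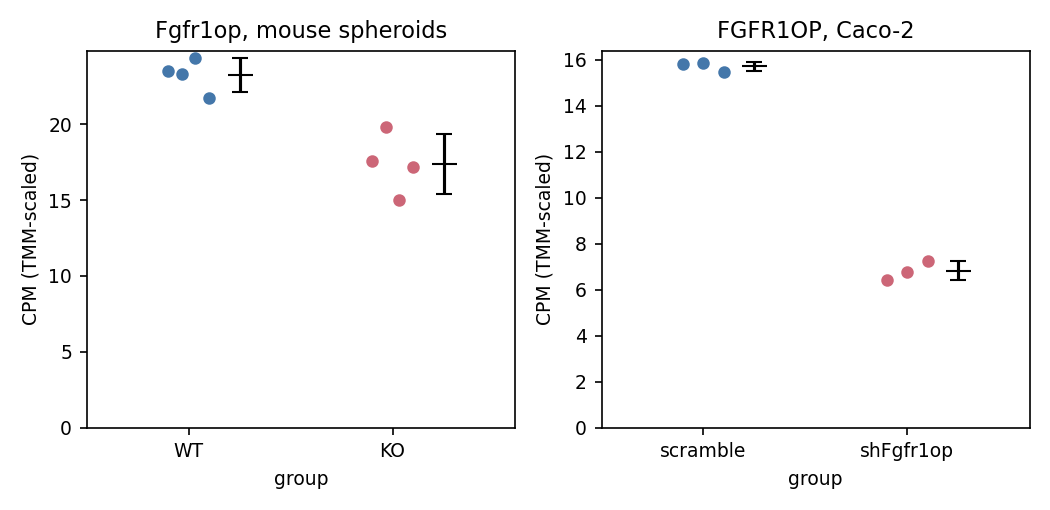
Fgfr1op level in CPM on TMM-scaled library sizes (y axis) in each group (x axis), for mouse spheroids on the left and Caco-2 on the right. Each point is 1 library and the black mark with its bar is the mean ± SD; KO and shFgfr1op libraries lie below all of their controls.

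In spheroids labelled KO the main edgeR fit called a small set of genes, most of them higher. Fits without the filter on low counts called more genes, with rises and falls nearer to balance. A short list of calls does not show that few genes changed. The largest rise among the genes named by rule was Esr1, which encodes oestrogen receptor alpha (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), at 16.95 ± 1.86 CPM in KO against 4.97 ± 1.03 in WT (SD, n = 4; log2 fold change 1.77 ± 0.15 SE). Its counts are per gene and do not show which exons the reads came from. Fam20c, a Golgi kinase of secreted proteins, rose by 1.00 ± 0.12 on the log2 scale. Ckb, the brain-type creatine kinase, rose from 134 ± 18.7 to 262 ± 39.7 CPM (0.96 ± 0.12). Sytl2, a protein of vesicle transport, rose by 0.83 ± 0.14 and did not pass under the stricter filter on low counts (adjusted p 0.0583), and Aldh1a3, which makes retinoic acid, by 0.77 ± 0.11. Jun, a subunit of the transcription factor AP-1, rose from 64.0 ± 6.24 to 108 ± 16.9 CPM (0.76 ± 0.11). The MAP kinase phosphatase Dusp8 rose by 0.69 ± 0.10, and Clca3b, of the Clca family of secreted proteins, by 0.70 ± 0.10.

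Falls that met the rule numbered 3. Naip6, a member of the family of sensors of bacterial proteins, was at 37.4 ± 3.72 CPM in KO against 63.5 ± 8.81 in WT (-0.76 ± 0.11). Plcd1, a phospholipase C, was at 14.3 ± 1.52 against 22.7 ± 2.72 CPM (-0.67 ± 0.11), and Mocs1, of molybdenum cofactor synthesis, at 34.3 ± 1.59 against 45.5 ± 2.71 CPM (-0.41 ± 0.068). Adjusted p from edgeR ran from 0.00199 for Esr1 to 0.0458 for Mocs1 and Sytl2. Over 15915 genes tested, edgeR called 37, of which 30 were higher and 7 lower in KO, and 9 changed at least 2-fold (5 higher, 4 lower). Groups did not overlap in 1363 genes, which is 8.56%, where chance gives 2.86%. An unadjusted edgeR p below 0.05 was found for 2325 genes, more than chance alone would give if no gene changed. The count moved with each library left out. It was 20, 11, 160 and 5 without KO replicates 1, 2, 3 and 4, and 6, 11, 3 and 8 without WT replicates 1, 2, 3 and 4. Of the genes named by rule that were called with all libraries, Esr1 was called in 8 of these 8 fits, Rhoc in 7, Fam20c in 5 and the others in 1 to 3. Gm13394 and Pianp, chosen after their values were seen, were also called in all 8. Esr1, Gm13394 and Pianp were the only 3 of the 37 genes called in every fit. For them, sources other than the loss of Fgfr1op stay open, as set out among the flagged results. For the other genes called, such sources were not excluded either. Gm13394, annotated as a processed pseudogene with 99.9% identity to Gapdh over 1000 bases, was at 200.5 ± 40.3 CPM in KO against 2.45 ± 0.18 in WT, and Pianp was at 1.17 ± 0.45 against 0.0672 ± 0.038. The fit without a filter on low counts called 154 genes (100 higher, 54 lower). DESeq2, which was also run without that filter, called 577 (310 higher, 267 lower). An absolute log2 fold change of at least 1 left 9 (5 higher, 4 lower).

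Of 42 tested genes of the actomyosin cytoskeleton 3 rose in KO spheroids and 39 did not pass, and adjusted over the list alone 18 rose. Rhoc and Rhou, GTPases that act on actin, were at 99.8 ± 5.65 against 63.3 ± 5.33 CPM (log2 fold change 0.66 ± 0.074) and at 96.2 ± 7.74 against 66.8 ± 2.56 CPM (0.53 ± 0.070). Zyx, the focal adhesion protein zyxin, was at 236 ± 22.1 against 159 ± 5.69 CPM (0.57 ± 0.076). The list had a median log2 fold change of 0.20 and an adjusted camera p of 1.31e-07, against adjusted p = 0.811 with an estimated correlation and an adjusted p of 0.10 by the directional test of fry. Junction genes had a median of 0.11 over 34 members (camera adjusted p 0.0291; adjusted p = 0.811 with an estimated correlation), with 0 members passed over all genes and 2 higher adjusted over the list alone. The junction call was lost without KO replicates 1 or 3 (0.0611 and 0.160) and without WT replicates 2, 3 or 4 (0.0545, 0.125 and 0.0868). Its leading members, the claudins Cldn4 (0.47 ± 0.11) and Cldn3 (0.29 ± 0.068), did not pass. Fetal-like and YAP target genes had a median of 0.27 over 28 members (camera adjusted p 2.26e-05; adjusted p = 0.811 with an estimated correlation). None of these passed over all genes and 10 were higher adjusted over the list alone, with Krt19 at 0.33 ± 0.082, Plaur at 0.26 ± 0.068 and Clu at 0.46 ± 0.13.

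Of 37 p53 target genes 1 rose, also adjusted over the list alone. It was Btg2, an antiproliferative gene, at 147 ± 9.31 CPM in KO against 103 ± 10.0 in WT, while Trp53inp1 (0.33 ± 0.086) and Bax (0.18 ± 0.058) did not pass. The p53 list had a median of 0.05 and a camera adjusted p of 0.0437, against adjusted p = 0.811 with an estimated correlation. Its call was lost without KO replicates 1, 2 or 3 (0.142, 0.0546 and 0.0665) and without WT replicates 1 or 3 (0.227 and 0.289), and with voom and sample quality weights (0.121), and its median ran from 0.006 (without WT replicate 3) to 0.10 (without WT replicate 4). Interferon response genes had a median of 0.28 over 30 members (camera adjusted p 0.0291; adjusted p = 0.811 with an estimated correlation), with 0 passed and 1 higher adjusted over the list alone. Parp14 was at 0.54 ± 0.11. Without KO replicate 1 the interferon median was -0.07 and its camera adjusted p 0.826, and the median was 0.56 without WT replicate 1, 0.17 with voom (adjusted p 0.0284) and 0.15 with the stricter filter (0.0392). The call was also lost without KO replicate 3 (0.0563) and without WT replicates 3 or 4 (0.289 and 0.158). G1/S genes of DNA replication had a median of 0.14 over 37 members (camera adjusted p 0.0232; adjusted p = 0.811 with an estimated correlation), with 0 passed on either scale, and Mcm5 was at 0.27 ± 0.12. The G1/S call was lost without KO replicate 2 (median 0.03, adjusted p 0.761) and without WT replicates 2 or 4 (0.0545 and 0.232), and the median was 0.21 without KO replicate 3. None of the 11 lists called in spheroids held with an estimated correlation, and the directional test of fry called 0 lists. Its mixed test, which asks whether the genes of a list change in either direction, called 8 of 28 lists, among them junction (2.69e-04), stem cell (6.99e-04) and actomyosin (0.00131).

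The 5 lists called as lower in KO spheroids held no member that passed over all genes, nor any adjusted over the list alone, and each had adjusted p = 0.811 with an estimated correlation. Glycolysis and hypoxia genes had a median log2 fold change of -0.33 over 31 members (camera adjusted p 1.99e-05; adjusted p = 0.811 with an estimated correlation). The median was -0.22 without KO replicate 2 and -0.51 without KO replicate 1. Vegfa was at 144 ± 46.8 CPM in KO against 211 ± 16.6 in WT, and the glycolytic enzyme Gpi1 had a log2 fold change of -0.53 ± 0.22. The unfolded protein response had a median of -0.15 over 25 members (5.34e-04; adjusted p = 0.811 with an estimated correlation), with the endoplasmic reticulum chaperone Hyou1 at -0.24 ± 0.069. Without KO replicate 1 its median was -0.23. The integrated stress response had a median of -0.21 over 28 members (0.00647; adjusted p = 0.811 with an estimated correlation), with Stc2 at -0.64 ± 0.23. This call was lost without KO replicates 1 or 2 (0.0611 and 0.171) and without WT replicate 4 (0.105). Its median was -0.12 without either of these KO replicates and -0.33 without KO replicate 3 or 4. Distal small intestine genes had a median of -0.63 over 18 members (0.00145; adjusted p = 0.811 with an estimated correlation), with Cd177 at 2.30 ± 1.02 CPM against 4.61 ± 1.06. WT replicate 1 stood apart from the other libraries, at -39.0 on the first principal component (31.4% of the variance) against -7.03 to 14.1. It alone had high counts of Xist (18489, against at most 6) and low counts of Y-linked genes (2, against at least 5691). Without it the distal median was -0.16 and the camera adjusted p 0.0777. Mitochondrially encoded genes had a median of -0.42 over 13 members (0.00419; adjusted p = 0.811 with an estimated correlation), and mt-Co1 was at 1955 ± 704 CPM in KO against 3277 ± 293 in WT. Mitochondrial genes took 0.50 ± 0.16% of counts in KO and 0.75 ± 0.05% in WT, with KO replicate 4 lowest at 0.277%. Without that library the median of the list was -0.23 (camera adjusted p 0.00313), and with voom and sample quality weights it was -0.70 (1.92e-05), while the distal median with voom was -0.41 (0.00307).

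Stem cell and centrosome lists were not called by camera or the directional test of fry in spheroids, and the mixed test of fry called the stem cell list. Of 22 stem cell genes 1 rose (Clca3b) and 21 did not pass, and adjusted over the list alone 3 rose and 5 fell. Ephb3 was at 0.32 ± 0.059 and passed with voom (adjusted p 0.0452) and without a filter on low counts (0.0458). Of 41 centrosome and centriole genes 0 passed, and Cep120 was at 0.35 ± 0.092 and Cep85 at -0.28 ± 0.097. Other splits of the 8 libraries into 4 and 4 also gave list calls, and 12 of the 35 splits, the real one included, called at least 11.

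**Figure D2:**
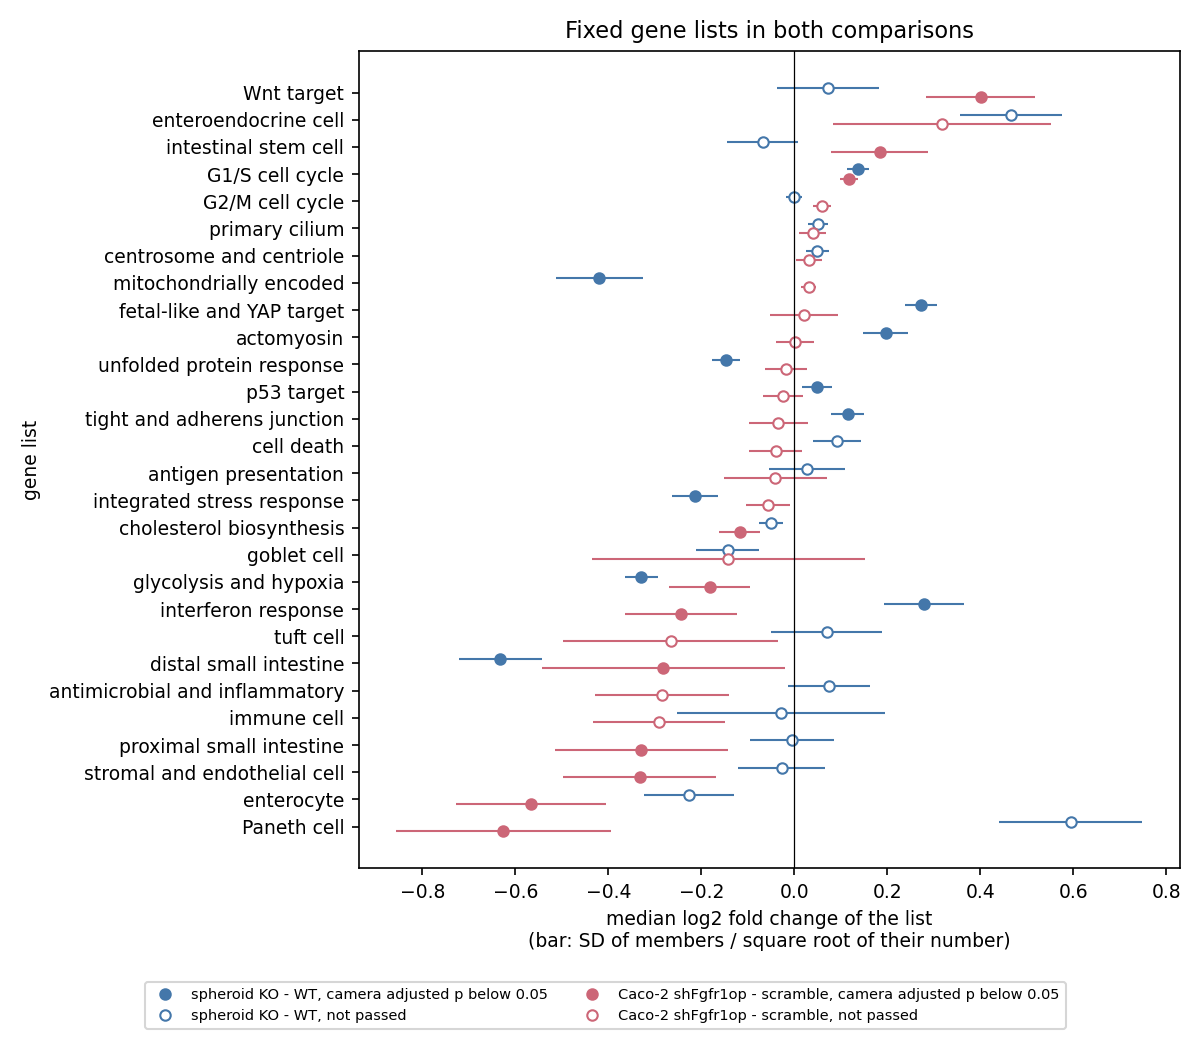
Median log2 fold change (x axis) of each of the 28 gene lists (y axis) in spheroids (KO against WT) and Caco-2 (shFgfr1op against scramble); bars are the SD of the members over the square root of their number. Filled points passed camera at the preset correlation and none of them passed with an estimated correlation; the enterocyte list lay at -0.57 in Caco-2.

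In Caco-2 cells with the Fgfr1op hairpin, 11 of 19 intestinal stem cell genes and 11 of 16 Wnt target genes rose, and 17 of 28 enterocyte genes fell. Camera called these 3 lists, but none held with an estimated correlation (adjusted p = 0.164, 0.188 and 0.232 with an estimated correlation). The estimates were -0.02, 0.04 and 0.17, so correlation between members does not account for the loss in the stem cell list. The lower degrees of freedom of that test also raise p. LGR5, the Wnt-potentiating receptor that marks crypt base stem cells, rose from 14.5 ± 1.03 to 40.7 ± 1.39 CPM (SD, n = 3; log2 fold change 1.48 ± 0.065 SE). The Wnt target SP5 rose from 70.6 ± 0.54 to 137 ± 9.12 CPM (0.96 ± 0.042). LCT, the brush border enzyme lactase, fell from 6.92 ± 0.37 to 1.01 ± 0.29 CPM (-2.78 ± 0.18), and CUBN, the receptor cubilin, from 34.4 ± 1.15 to 9.17 ± 0.32 CPM (-1.91 ± 0.072). Of 18905 genes tested edgeR called 6031, of which 2966 were higher and 3065 lower, and 562 changed at least 2-fold (291 higher, 271 lower). The median size of a called log2 fold change was 0.30, so most changes were small. Groups did not overlap in 8008 genes (42.4%, where chance gives 10%).

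The intestinal stem cell list had 19 tested members, of which 11 rose, 1 fell and 7 did not pass. Adjusted over the list alone, 12 rose and 1 fell. TNFRSF19, a receptor of the tumour necrosis factor family, rose by 0.58 ± 0.046 and PROM1, which encodes CD133, fell by 0.32 ± 0.030. Of 16 Wnt target genes 11 rose and 2 fell, the same numbers as adjusted over the list alone. NKD1, a feedback inhibitor of Wnt signalling, rose by 0.93 ± 0.058 and the cyclin CCND1 by 0.43 ± 0.033. G1/S genes rose in 17 of 37 members and fell in 2, against 19 and 2 adjusted over the list alone, by small amounts (PCNA 0.25 ± 0.039, MCM5 0.21 ± 0.036). These 3 lists were called higher with camera adjusted p of 0.00126, 5.87e-04 and 0.0029. With an estimated correlation the adjusted p were 0.164, 0.188 and 0.665, and none held. The directional test of fry did not call the G1/S list (0.0937) and called the other two.

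Of 28 enterocyte genes 17 fell, 1 rose and 10 did not pass, with the same numbers adjusted over the list alone. The peptidase DPP4 fell from 303 ± 4.19 to 188 ± 4.86 CPM (-0.69 ± 0.032). Proximal small intestine genes fell in 9 of 15 members and rose in 0, with the same numbers adjusted over the list alone. The ferroxidase HEPH fell by 1.13 ± 0.060. Distal small intestine genes fell in 5 of 10 and rose in 1, against 6 and 1 adjusted over the list alone, with SLC51B, a bile acid transporter, at -1.72 ± 0.13. LCT was also a member of the proximal list and CUBN of the distal list. The enterocyte, proximal and distal calls therefore partly rest on the same genes. Of 7 Paneth cell genes 5 fell and 0 rose on both scales, with LYZ, which encodes lysozyme, at 16.8 ± 0.71 against 24.96 ± 1.68 CPM. Among the genes named by rule there, the largest fall was HABP2 (-1.59 ± 0.056), a serine protease that liver cells also make. Camera adjusted p were 9.99e-07 for enterocyte, 5.43e-04 for proximal, 0.0126 for distal and 8.56e-04 for Paneth genes. With an estimated correlation the adjusted p were 0.232, 0.164, 0.278 and 0.164. Without scramble replicate 2 the distal list had a camera adjusted p of 0.0547. The distal median of -0.28 was -0.61 without a filter on low counts. The Paneth median of -0.63 was -0.95 without scramble replicate 1, and -1.12 and -0.97 without shFgfr1op replicates 2 and 3, and the proximal median of -0.33 was -0.54 without shFgfr1op replicate 2.

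Interferon response genes fell in 10 of 22 members and rose in 1, with the same numbers adjusted over the list alone. IFIT3 was at 4.59 ± 0.54 against 12.4 ± 1.71 CPM, and PARP14 fell by 0.42 ± 0.049. Glycolysis and hypoxia genes fell in 23 of 32 members and rose in 4, against 24 and 5 adjusted over the list alone. GPI fell by 0.39 ± 0.029 and VEGFA by 0.46 ± 0.039, while the glucose transporter SLC2A3 rose from 2640 ± 47.4 to 3582 ± 127.9 CPM. Cholesterol biosynthesis genes fell in 14 of 25 and rose in 3 on both scales, with HMGCS1 at -0.53 ± 0.033 and TM7SF2 at 0.59 ± 0.040. Of 17 stromal and endothelial markers 7 fell and 3 rose on both scales. They included VIM (-1.32 ± 0.072), PDGFRB (-1.59 ± 0.087) and SPARC (-0.89 ± 0.059), at 12.8, 7.74 and 25.01 CPM in shFgfr1op. Camera adjusted p were 0.0233, 8.56e-04, 0.0126 and 0.0111 for these 4 lists. With an estimated correlation the adjusted p were 0.213, 0.417, 0.455 and 0.188. Without shFgfr1op replicate 3 the cholesterol list had a camera adjusted p of 0.0652.

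The goblet cell, centrosome, actomyosin, junction and p53 lists were not called by camera in Caco-2, and their members moved both ways. By the directional test of fry, which does not compare a list with other genes, the goblet and junction lists were called lower (adjusted p 0.00274 and 0.00155) and the centrosome list higher (0.00826). Of 13 goblet genes 5 fell and 2 rose on both scales, among them ZG16 (-2.14 ± 0.11) and AGR2 (-0.81 ± 0.039). Of 41 centrosome and centriole genes 10 rose and 3 fell on both scales, with MAPRE1, which encodes the microtubule end-binding protein EB1, at 0.42 ± 0.032 and CEP57 at 0.42 ± 0.039. Of 42 actomyosin genes 13 rose and 13 fell, and adjusted over the list alone 13 rose and 15 fell. MYL12A was at 0.57 ± 0.041 and MYO1A, a brush border myosin, at -1.21 ± 0.11. Of 34 junction genes 9 rose and 11 fell, and 9 and 12 adjusted over the list alone, with CDH17 at -0.86 ± 0.035, CLDN1 at -0.77 ± 0.037 and CLDN4 at -0.36 ± 0.033. Of 32 p53 targets 8 rose and 7 fell on both scales, with ZMAT3 at 0.51 ± 0.084 and TNFRSF10B at -0.32 ± 0.047. The p53 and actomyosin medians (-0.02 and 0.002) had the opposite sign to camera's direction, at camera adjusted p of 0.979 and 0.90.

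The largest rise among the genes named by rule was ATP1B2, a subunit of the sodium-potassium pump. It was at 227 ± 25.04 CPM in shFgfr1op against 1.17 ± 0.13 in scramble (7.58 ± 0.14, edgeR adjusted p 1.09e-08). The next were ENOX1 (2.06 ± 0.079), LOXL4 (1.56 ± 0.089) and PROM2 (1.51 ± 0.16). Among falls, PHGR1 was at -1.84 ± 0.080 and HSD3B1, an enzyme of steroid synthesis, at -1.76 ± 0.051. LGI4 was at -1.98 ± 0.37 with an adjusted p of 0.0153, and it did not pass without shFgfr1op replicate 3 (0.0755).

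**Figure D3:**
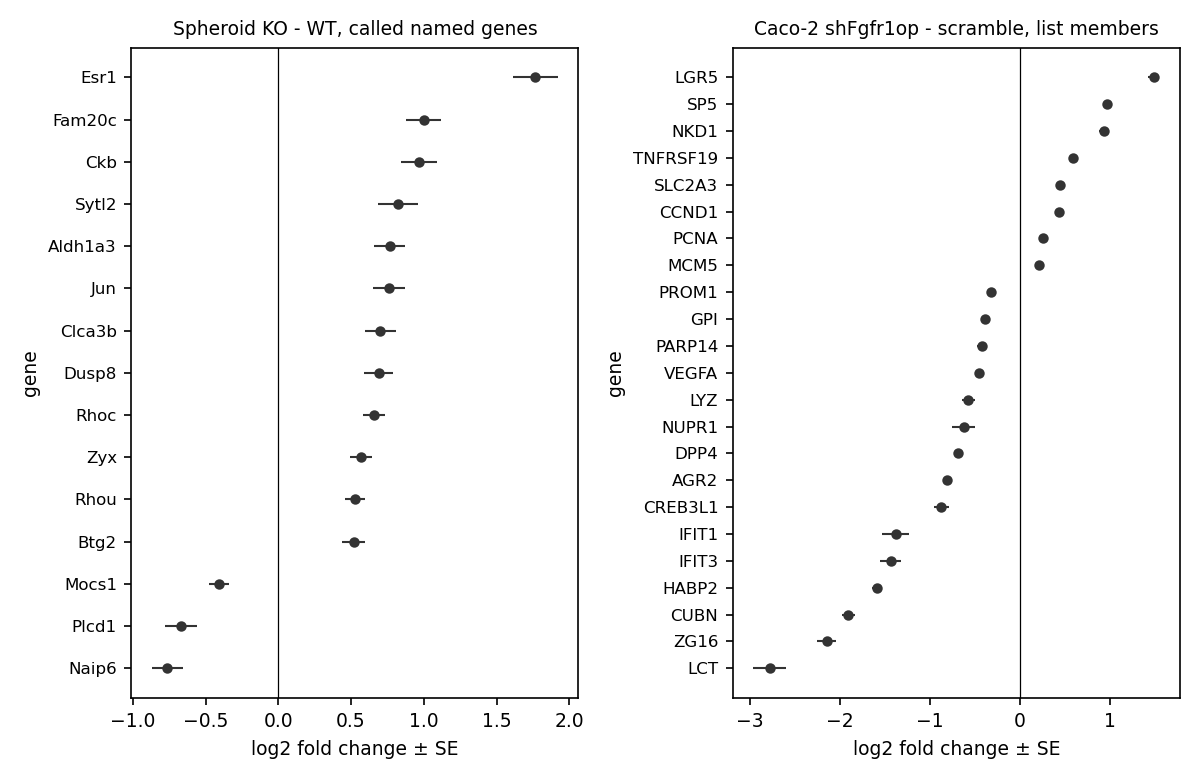
Log2 fold change ± SE (x axis) of genes named by rule (y axis), for spheroid KO against WT on the left (genes that passed) and for Caco-2 shFgfr1op against scramble on the right (reported members of 8 lists). Esr1 at 1.77 lies highest on the left, and on the right LGR5 lies at 1.48 and LCT at -2.78.

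The calls of the spheroids and Caco-2 were set side by side over 10879 genes with the same upper-case symbol. Of 24 genes higher in KO spheroids 2 were also higher in Caco-2 (FAM20C and MXD4), where independent lists would share 5.23 (two-sided Fisher's exact p across genes 0.138). Of the same 24 genes, 7 were lower in Caco-2, where independent lists would share 4.84 (Fisher's exact p 0.305). These were CKB, ZYX, DUSP8, DUSP16, SYTL2, FILIP1L and JUND. Of 5 genes lower in KO spheroids 1 was higher in Caco-2 (MOCS1; 1.09 expected, Fisher's exact p 1) and 0 were lower (1.01 expected, Fisher's exact p 0.59). No overlap passed, and genes are not independent of each other. MXD4, DUSP16, FILIP1L and JUND were named after their values were seen. Across the matched genes the log2 fold changes had a Pearson correlation of 0.037.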

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

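Tests chosen after the result was seen were those of Gapdh reads at Gm13394, of the haplotype around Gapdh, of a joint rise of glycolytic genes, of recombinase reads at Esr1, of the interferon response to the hairpin and of other differences between the Caco-2 populations. The first pattern was extended to Esr1 after its values were seen.

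In 2 of 110 groups of 4 values, 1 library lay far from the others, where chance gives about 5.5. The values were those of named genes, the target, measures of library depth and content, and principal components. Fam20c in WT replicate 4 was at 7.422 CPM, and the other WT libraries were at 5.671 to 5.816. Zyx in WT replicate 1 was at 150.903 CPM, and the other WT libraries were at 162.0 to 162.6.

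Of 100 reported named genes measured in both systems, 10 moved one way in every KO spheroid library and the opposite way in every shFgfr1op library, each set against all of its controls. These differences between mouse spheroids and a human line were not tested. Genes were named partly for small p or for no overlap. Over all genes tested, groups did not overlap in 8.56% in spheroids and 42.4% in Caco-2. How many named genes moved the same way in both was not counted, so the 10 do not show an opposition between the systems. The spheroid log2 fold change minus that of Caco-2 was 1.83 for CKB, 1.61 for SYTL2, 0.97 for PARP14 and 0.92 for DUSP8. It was 0.83 for CLDN4, 0.83 for CLU, 0.72 for ZYX, 0.65 for TAPBP and 0.47 for KRT19. For MOCS1, lower in KO spheroids and higher in Caco-2, it was -0.69. Of these, CLDN4, CLU, KRT19, PARP14 and TAPBP did not pass in spheroids by edgeR with all libraries and the filter on low counts. CLDN4 passed without the filter (adjusted p 0.0235) and without KO replicate 3 (0.0481), and PARP14 passed without the filter (0.0215) and with voom (0.0467).

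In KO spheroids Gm13394, at chromosome 2, 28933610 to 28934609, was at 200.5 ± 40.3 CPM (SD, n = 4) against 2.45 ± 0.18 in WT, and Eno2 (6.73 ± 5.82 against 0.126 ± 0.079), Pianp and BC064078 on chromosome 6, which also holds Gapdh, rose as well, as did Esr1; all but Esr1 were chosen after their values were seen. A joint rise of glycolytic genes is argued against, since that list had a median log2 fold change of -0.33 and Gapdh itself was at 3135 ± 583 against 4306 ± 491 CPM. The ratio of Gm13394 to Gapdh varied by 2.02% over the KO libraries (coefficient of variation), against 20.1% for Gm13394 alone, at 6.38 ± 0.129% of Gapdh in KO and 0.0572 ± 0.0049% in WT, so Gapdh reads counted at a copy with 99.9% identity are a candidate source, for instance with a variant in the KO mice. A separate haplotype near Gapdh predicted a share of changed genes among the highest 5% of 473 windows (at most 23 windows with as high a share). So did flanking DNA of the targeted gene on chromosome 17. The risen genes lie on chromosomes 2, 6 and 10, which argues against flanking DNA of chromosome 17 as a direct source of their rises. Both shares missed the highest 5%, with 27 and 30 such windows. The overlapping window from 125 to 135 Mb on chromosome 6 ranked 10, however. Other windows of chromosome 6, within 15 to 25, 35 to 50, 65 to 80 and 130 to 145 Mb, also ranked between 9 and 23. High shares on this chromosome were thus not limited to the region of Gapdh, and their cause was not tested. The exact 95% intervals (4.85% to 17.5% and 3.13% to 20.7%) held the edge of 10.2%, a criterion added after these numbers were seen. For both it therefore stays open whether the share lies among the highest 5%. Over all genes the share was 4.78%, below the first interval and within the second. Reads of a recombinase fused to an oestrogen receptor domain could add to Esr1, which was 11.98 CPM higher in KO, and counts per gene do not decide this, so the genotype's own effect on Esr1 stays open too.

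WT replicate 1 of the spheroids lay apart from the other libraries and was the library with Xist (18489 counts) and almost without Y-linked counts (2). Lower depth is argued against, since its distance to the other WT libraries was 1.24 times the highest of theirs with all genes and 1.23 times at equal totals. Without chromosomes X and Y it was 1.18 times, still the highest of the WT group but below the 1.2 times set to exclude a difference in sex-linked expression, so that stays open. Its mean log2 CPM of distal minus proximal small intestine genes was 0.616, outside the -0.479 to 0.171 of the other 7 libraries, which is consistent with an origin in a more distal segment. Sex and segment are confounded in this 1 library, and no label used here gives either.

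In Caco-2, 6031 genes were called, with a median size of 0.30 on the log2 scale. Depth is argued against as the cause, since 5925 genes (98.2%) were called at equal totals. With the 100 most abundant genes, which took 24.7% of counts, left out of the scaling, 6034 genes were called. TMM already trims the most abundant genes and the largest ratios. This test could therefore hardly move the count, and it does not decide on scaling. A stronger interferon response in shFgfr1op than in scramble is argued against by a median of -0.24 in the interferon list. Both groups carried a hairpin, so a response shared by both, or stronger in scramble, stays open. With 1 hairpin against the target, another difference between the transduced populations cannot be told apart from the effect of the knockdown, and the rise of ATP1B2 from 1.17 to 227 CPM may belong to either. Off-target effects of the hairpin were not tested.

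Of the 35 splits of the spheroid libraries into 4 and 4, only the real one (1 split) gave 37 genes, and the highest of the others gave 1. A share of 1 in 35 is the smallest that these splits can give, so chance is argued against there but not excluded. For gene lists chance cannot be excluded, since 12 of the 35 splits gave at least the 11 lists of the real split, and the highest other gave 15. In Caco-2 there are only 10 splits, too few for a share under 0.05. The real one gave 6031 genes and 11 lists, and the highest of the others gave 0 and 7.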

How the results depend on the processing

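All alternatives here were planned except DESeq2 for the target gene, which was chosen after seeing the data. For spheroids, the 37 genes called became 154 without a filter on low counts, 577 with DESeq2 and 9 at an absolute log2 fold change of at least 1, and 3 to 160 when 1 library was left out (lowest without WT replicate 3, highest without KO replicate 3). DESeq2 was run without filterByExpr, on 27088 genes as in the fit without a filter, against 15915 in the main fit. The filter and the test thus changed together there, also in Caco-2. RLE size factors gave 36, the stricter filter 30 and voom 55. All 37 genes were among the DESeq2 calls, with the same direction. Fgfr1op in spheroids had a log2 fold change of -0.42 with DESeq2, where it passed at an adjusted p of 0.00609, and its adjusted p ran from 0.0645 to 0.288 in the other alternatives. Of the 11 spheroid lists, 0 were called with an estimated correlation and 0 by the directional test of fry, and 7 to 11 stayed called when 1 library was left out (7 without KO replicate 1 or WT replicate 4). The interferon median ran from -0.0693 (without KO replicate 1) to 0.558 (without WT replicate 1). In Caco-2 the 6031 genes became 562 at an absolute log2 fold change of at least 1, and 5123 to 6334 in the other alternatives, and 4052 genes were called in all 6 fits that left out a library. Of the 11 Caco-2 lists 0 were called with an estimated correlation, and 10 or 11 stayed called in each of the other alternatives. Over all 28 lists the directional test of fry called 15, 10 of them among the 11. The mixed test called 8 lists in spheroids and 27 in Caco-2. With calls at 0.01 the shared genes in the same and in opposite directions were 0 and 0, against 2 and 8, but no matched spheroid gene passed at 0.01, so there was nothing to share. The causes were not tested, except that a stricter threshold lowers a count by construction.

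With the replicate number as a block, 71 spheroid genes were called, 30 of them among the 37, and 5904 in Caco-2. Deviations of samples with the same number correlated weakly (-0.03, 0.02, 0.07 and 0.10 in spheroids and 0.04, 0.01 and 0.003 in Caco-2). In spheroids no KO sample correlated best with the WT sample of its own number. In Caco-2, shFgfr1op samples 1 and 2 did so with scramble, and sample 3 did not. These values show no clear pairing by number but cannot exclude a weak shared batch. Of 47 named spheroid genes 44 stayed on the same side of the threshold under the block, and of 85 in Caco-2 84 did. The calls that ended were those of Jun, Dusp8 and Mocs1 (each at an adjusted p of 0.0540 by edgeR) and of LGI4 (0.0991). The p53 and junction lists in spheroids lost their call under it (both at an adjusted p of 0.0523). The alternatives listed for the crypt comparisons were not run.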

Other observations

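No test in this part was chosen after the result was seen. Of 39 G2/M genes in Caco-2 8 rose and 5 fell, and 9 and 6 adjusted over the list alone, among them the cytokinesis genes ANLN (0.30 ± 0.038) and ECT2 (0.23 ± 0.040). Of 42 primary cilium genes 6 rose and 2 fell, and 5 and 2 adjusted over the list alone. The kinesin-2 motor subunits went opposite ways, with KIF3B at -0.34 ± 0.034 and KIF3A at 0.34 ± 0.069. Antimicrobial and inflammatory genes fell in 6 of 14 members and rose in 2 on both scales, with DUOX2, an oxidase of the epithelial surface, from 11.2 to 5.76 CPM and the cytokine IL18 from 23.9 to 16.5 CPM (camera adjusted p 0.0834, directional fry 6.94e-04). Of 10 tuft cell genes 2 rose and 3 fell, of 9 enteroendocrine genes 0 and 2, and of 12 immune cell genes 0 and 2, on both scales. Of these 3 lists camera called none and the directional test of fry the tuft cell list, as lower (adjusted p 0.00767). Unfolded protein response genes rose in 2 and fell in 3 of 25, with the chaperone HSPA5 at -0.40 ± 0.030. Integrated stress response genes rose in 2 and fell in 8 of 26, with MTHFD2 at 0.57 ± 0.049 and PSPH at -0.49 ± 0.042. Fetal-like and YAP target genes rose in 6 and fell in 5 of 21 (7 and 5 adjusted over the list alone), with ANKRD1 at 0.53 ± 0.067. Antigen presentation genes rose in 1 and fell in 5 of 17, and cell death genes rose in 6 and fell in 7 of 25. The numbers for the unfolded protein, integrated stress, antigen presentation and cell death lists were the same adjusted over the list alone. Of 12 mitochondrially encoded genes 0 passed, and their share of counts was 11.74 ± 1.01% in shFgfr1op and 11.27 ± 0.69% in scramble.

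In spheroids, markers of differentiated cells did not pass as lists by camera or the directional test of fry. Paneth cell genes had a median log2 fold change of 0.59 over 13 members (camera adjusted p 0.164) and enteroendocrine genes 0.47 over 19 (0.201). Goblet genes had a median of -0.14 over 21 members (0.195) and enterocyte genes -0.23 over 32 (0.325). None of these members passed. Wnt target (0.07), tuft cell (0.07), antimicrobial (0.07), primary cilium (0.05), G2/M (-0.0003), cholesterol (-0.05), proximal (-0.004), immune (-0.03) and stromal (-0.03) medians lay nearer to 0, and none of these lists was called by camera or the directional test of fry. The mixed test of fry called the Wnt target, tuft cell, immune and antigen presentation lists (adjusted p 0.0495 each) and the antimicrobial list (0.0423). Adjusted over the list alone, 1 Wnt target, 1 tuft cell, 1 antigen presentation and 3 antimicrobial genes were higher and 1 Wnt target and 2 immune genes lower in KO. The antigen presentation list had a median of 0.03 and a mean of -0.02, and the cell death list 0.09 and -0.02, so median and mean differed in sign in both.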
